A study of Mus musculus with 6 samples.

How the data were processed

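Total RNA of kidney tissue was extracted with Trizol, amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. There were 2 groups of 3 samples, sham and ischemia-reperfusion (IR), assigned from the sample titles, with kidneys taken at 24 h and a clamp of 30 min in the IR group. The file headers name Agilent array design 055750 and the mouse build mm9. Per the file headers and the submitters' processing notes, the authors extracted the scans with Agilent Feature Extraction 11.0.1.1. The deposited scanner files give, per spot, a processed signal intensity, which per the file headers is background-subtracted and spatially detrended but not scaled between arrays, the median spot and background intensity, and flags for saturation, outliers and signal well above background. The authors' deposited values for the whole series are on a log scale that no header states. Their 60902 rows matched probe names. Across probes, each column correlated with the log2 processed signal of the same array at r between 0.9964 and 0.9997, with a slope between 0.9411 and 0.9827, so these deposited values were taken as log2. The column medians were 4.903 in 4 arrays and 4.904 in IR replicates 1 and 3, which are the near-equal medians that a normalisation between arrays gives. The centring and the exact normalisation stay unknown. All 6 arrays came from 1 slide and 1 scan. The IR arrays and sham replicate 1 were in row 1 of the slide and sham replicates 2 and 3 in row 2.

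The values tested were log2 of the processed signal minus the 75th percentile of each array, averaged over the spots of a probe. Control spots and outlier spots were left out, as were 15 negative probes (300 spots) that the files do not mark as controls, a choice made after the data were examined. No spot was saturated, so the number of saturated spots per array was 0. A probe with several spots counted as well above background where at least 0.5 of its spots were, also set after the data were examined. A probe was tested if it was well above background on all 3 arrays of at least 1 group. A further 55 probes with a missing value on an array were dropped. IR was compared with sham by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 35540 probes and a threshold of 0.05. Intervals are 95% intervals of that fit. An exact permutation test of 3 against 3 samples cannot give a p below 0.1 and was not used. Figures were drawn with matplotlib 3.10.9.

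On simulated data with the spread of the real samples and 35540 probes, the fit of IR against sham recovered 31.3% of probes changed 2-fold, 80.6% of those changed 4-fold and 93.9% of those changed 16-fold, with 5 false calls. The simulated changes were put on random probes, with noise drawn independently for each probe and array. The simulation therefore held no structure shared between probes of an array and no link between the size of a change and its spread. These percentages do not say what share of real changes could be found here. The precision of every value is limited by the number of arrays and, for dim probes, by the signal over background.

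Probe names came from the scanner files alone. Of the accessions in these files, 15 RefSeq mRNA accessions, each on 1 probe, were looked up without versions among the RefSeq genes of assembly GRCm38.p6, and 15 matched a symbol. Because that assembly differs from the build of the array design, no positions are given. Other probes were classed only by the form of their IDs, with 1836 named for lincRNAs. These stood for the non-coding probes and the accession probes for the coding probes of the planned counts. A gene name for the remaining probes was not used here. The rule fixed before the data were examined named the genes with the widest differences among those past the threshold, up to 4 members of each gene list and 11 genes in every case. It could name only Hsp90ab1, as a list member. All 15 genes with a name were therefore reported, together with 4 probe IDs, the widest differences in each direction among probes with separated groups that were well above background on at least 1 array of each group, all chosen after the values were seen. The gene list tests (limma camera and fry) were not run because 0 of the 29 lists had 5 named genes.

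The alternatives planned before the data were examined were quantile normalisation, a shift by the median, no filter on dim probes, a filter on all 6 arrays, the authors' log2 values, the replicate number as a block, eBayes with trend and robust settings, array weights, a 2-fold minimum, a threshold of 0.01 and leaving out each array. Alternatives added after the data were examined were normexp background correction with an offset of 50 on the median signal (with either normalisation), the row of the array as a block, row 1 alone, and as a block the split of sham replicate 1, IR replicate 1 and IR replicate 3 from the other arrays. The method for array weights was changed to the gene-by-gene one after the default had failed to converge. Splits of the 6 arrays into other groups of 3, of which there are 10 with the real one, were fitted in the same way. Standard errors of correlations and slopes across probes came from 200 bootstrap draws of probes.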

Results

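RNA of 6 kidney samples from male mice was measured on 1-colour Agilent arrays carrying probes for long non-coding RNAs and mRNAs. In the ischemia-reperfusion (IR) group, both renal pedicles had been clamped for 30 min and then released, and the kidneys were taken 24 h later. The sham group had the same surgery without the clamp. Each group had 3 kidney samples with 1 array each. The labels do not say whether the samples of a group came from separate litters or cages, so p-values measure only the spread between these samples, which may be partly technical. Each array held 62939 spots, and 60915 probes remained after control and negative probes were set aside. The 75th percentile of the processed signal was 221, 167 and 158 in sham replicates 1, 2 and 3, and 225, 239 and 236 in IR replicates 1, 2 and 3. The number of probes well above background was 38365, 33882 and 32311 in the sham arrays and 38270, 37780 and 38254 in the IR arrays. Across replicates the number of arrays, 3 per group, limited the precision.

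The comparison of IR with sham asks which transcripts differ in the kidney 24 h after ischemia. Among the genes that could be named, the transferrin receptor Tfrc, which carries iron into cells, was 1.36-fold higher in IR, and the alpha-tubulin gene Tuba1b, a microtubule component, was 1.5-fold higher. Glycerol kinase, Gk, which phosphorylates glycerol, was 1.74-fold lower in IR. For each of these 3 genes, all 3 IR values lay on one side of all 3 sham values, but none passed the adjusted threshold. The other named genes, most of them common reference genes, differed less or overlapped between the groups. Names came from RefSeq accessions, which only 15 probes carried, and these genes were therefore named after the data had been examined.

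Tfrc (probe for NM_011638.3) had a normalised log2 signal of 7.88 ± 0.0833 (SD, n = 3) in IR and 7.44 ± 0.154 (SD, n = 3) in sham. The difference was 0.44 with a standard error of 0.138 (95% interval 0.11 to 0.77; limma, Benjamini-Hochberg adjusted p = 0.211). Tuba1b (NM_011654.2) averaged 8.55 ± 0.352 (SD, n = 3) in IR and 7.97 ± 0.107 (SD, n = 3) in sham. Its difference was 0.58 with a standard error of 0.198 (95% interval 0.11 to 1.05; limma, Benjamini-Hochberg adjusted p = 0.214). Gk (NM_008194.3) averaged 2.99 ± 0.56 (SD, n = 3) in IR and 3.79 ± 0.0571 (SD, n = 3) in sham, a difference of -0.80 with a standard error of 0.273 (95% interval -1.44 to -0.15; limma, Benjamini-Hochberg adjusted p = 0.215). Adjusted over the list alone of 14 named genes tested, the smallest limma p was 0.108, shared by Tfrc, Tuba1b and Gk, so 0 passed. The IR values of Gk were 3.51, 2.40 and 3.05 in replicates 1, 2 and 3, so replicate 2 was farthest from the sham values of 3.73, 3.77 and 3.85, and the difference was -0.50 without IR replicate 2 and -1.06 without IR replicate 1. For Tuba1b, IR replicate 2 was likewise farthest from sham, at 8.85, and IR replicate 1 was nearest, at 8.17. With the row of the array on the slide as a block, the difference was 0.31 for Tfrc, 0.58 for Tuba1b and -0.75 for Gk (limma, Benjamini-Hochberg adjusted p = 0.727 for each). Within row 1, where 3 IR arrays lay beside sham replicate 1, the differences were the same as with the block. Row 2 held only sham arrays and gave no comparison.

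**Figure D1:**
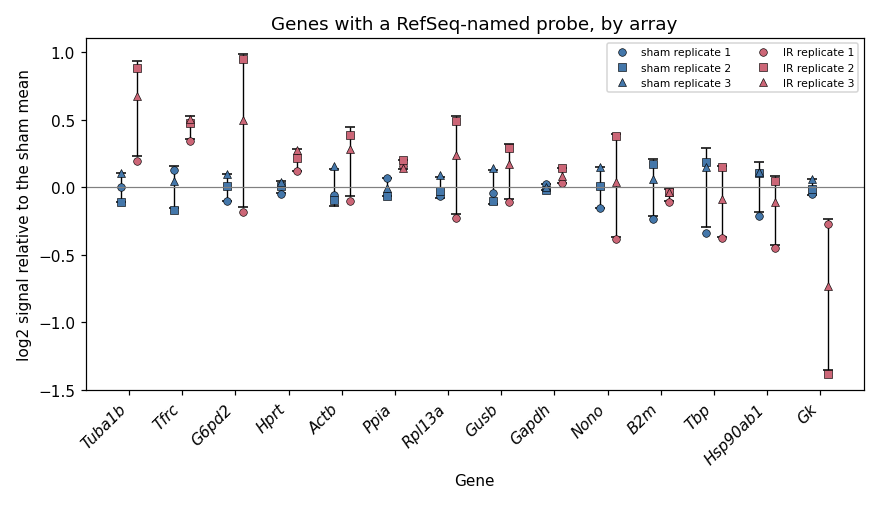
Normalised log2 signal of the 14 tested genes with a RefSeq-named probe, on the vertical axis relative to the mean of the sham arrays of that gene, with genes along the horizontal axis. Points are single arrays, bars span the group mean ± SD (n = 3). The IR points of Tuba1b, Tfrc and Gk lie clear of the sham points, and IR replicate 3 lies between the other IR replicates in 11 of the 14 genes.

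The glucose-6-phosphate dehydrogenase copy G6pd2 was 1.34-fold higher on average in IR, a log2 difference of 0.42 (limma, Benjamini-Hochberg adjusted p = 0.405), but IR replicate 1 lay below every sham array, and the difference was 0.72 without IR replicate 1 and 0.157 without IR replicate 2. The probe may also bind the transcript of the closely related G6pdx gene, so its identity is uncertain. Hprt, of purine salvage, differed by 0.20 and the prolyl isomerase gene Ppia by 0.17, with separated groups for both, although the sign for Ppia turned in the authors' values. For Hprt the difference fell to 0.0944 with quantile normalisation and to 0.106 in the authors' values. Gapdh, of glycolysis, differed by 0.09, also with separated groups, and its sign turned with quantile normalisation, where the difference was -0.08. The mouse GAPDH control probes were not tested. The one with the suffix 5 was at 6.974, 6.824 and 6.913 in sham replicates 1, 2 and 3 and at 7.018, 7.374 and 7.235 in IR replicates 1, 2 and 3. In the same order, the one with the suffix 3 was at 8.368, 8.409 and 8.448 in sham and at 8.407, 8.621 and 8.487 in IR. None of Hprt, Ppia and Gapdh passed (limma, Benjamini-Hochberg adjusted p = 0.361, 0.427 and 0.677). The beta-actin gene Actb differed by 0.19, the ribosomal protein gene Rpl13a by 0.17, the lysosomal enzyme gene Gusb by 0.115 (limma, Benjamini-Hochberg adjusted p = 0.534, 0.64 and 0.678), with overlapping groups in all 3. Without IR replicate 2 these differences were 0.0915 for Actb, 0.00457 for Rpl13a and 0.0286 for Gusb, and without IR replicate 1 they were 0.334, 0.362 and 0.229. The RNA-binding protein gene Nono, at 0.01, ranged from -0.173 without IR replicate 2 to 0.207 without IR replicate 1. Lower means in IR were found for B2m, the light chain of MHC class I, at -0.06, for the TATA-binding protein gene Tbp at -0.11 and for the cytosolic chaperone gene Hsp90ab1 at -0.17 (limma, Benjamini-Hochberg adjusted p = 0.827, 0.781 and 0.589). With the row as a block, the signs of B2m, Tbp and Hsp90ab1 turned, to 0.17, 0.23 and 0.04. These values set the IR arrays against sham replicate 1 alone, since row 2 held only sham arrays. Without the block, the differences of these 3 genes also moved with single arrays. B2m lay between -0.177 (without sham replicate 1) and 0.0265 (without sham replicate 2). Tbp lay between -0.274 (without sham replicate 1) and 0.0298 (without IR replicate 1), and Hsp90ab1 between -0.28 (without IR replicate 2) and -0.032 (without IR replicate 1). In all, 10 of the 14 genes had a higher mean in IR and 4 a lower one, and 6 had separated groups, but the signs of B2m, Gapdh, Hsp90ab1, Nono, Ppia and Tbp turned in 1 or more alternative settings. The lactate dehydrogenase copy Ldhal6b was not well above background on any array. Each of these genes had 20 spots per array, whose standard deviation within an array was between 0.0317 and 0.0703 log2 units for the tested genes, below the SD between samples for most of them.

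The 29 gene lists fixed before the data were examined covered 577 genes, among them markers of tubular injury, nephron segments, immune cells and metabolism. Of these genes 1, Hsp90ab1, had a named probe other than a control probe, so 0 lists reached the minimum of 5 genes and no list was tested. Pgk1, of the hypoxia and glycolysis list, had named control probes, which were left out. None of the 11 genes meant to be reported in every case, among them Havcr1, Lcn2, Umod and Slc34a1, had a named probe, and their levels are not analysed here.

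Over the whole array, 35540 probes (58.3%) were well above background on all arrays of a group and were tested. At an adjusted p under 0.05, limma with Benjamini-Hochberg adjustment called 0 probes higher and 0 lower in IR, with a smallest adjusted p of 0.151. At an unadjusted p under 0.05 there were 7042 probes (19.8%), of which 3056 had a higher mean in IR and 3986 a lower mean. This number moved with single arrays, to 10583 without sham replicate 1, 3826 without sham replicate 2, 3435 without sham replicate 3, 8624 without IR replicate 1, 4470 without IR replicate 2 and 3519 without IR replicate 3. The estimated share of unchanged probes was 65.3%. The groups did not overlap for 3484 probes with higher and 5673 with lower IR values, together 25.8%. The average over all 10 splits of the arrays is 10% whatever the data hold. Single splits can lie above it for other reasons, among them the row, so the excess does not by itself show an effect of IR. Mean differences of at least 2-fold were unevenly divided, with 1208 probes higher in IR and 362 lower. The imbalance was widest among dim probes, with 599 higher and 131 lower among the 11847 probes of lowest mean signal, against 207 and 121 among the 11847 of highest mean signal. Over all tested probes, differences of at least 2-fold with an unadjusted limma p under 0.05 numbered 867 higher and 297 lower. A further asymmetry was seen at the detection limit, where 355 probes were well above background on all 3 IR arrays and on no sham array, and 14 the other way round. Sham replicates 2 and 3, in row 2, had the lowest signal on the slide, while sham replicate 1 had the most probes well above background of any array. A fit with the row as a block sets the IR arrays against sham replicate 1 alone. With the row as a block, 2345 probes had an unadjusted p under 0.05, with 1 probe called higher and 1 lower.

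Most probes named for long intergenic non-coding RNAs were not bright enough to be tested. By the start of their IDs, 1104 of the 1836 on the array were named for human lincRNAs, 649 for mouse lincRNAs and 83 for exons of mm9 lincRNAs. How far the human-named probes match mouse transcripts is not given in the sources used here. Their dimness and counts therefore say little about the level of mouse lincRNAs. The share bright enough to be tested was 20.2% of the human-named, 22.3% of the mouse-named and 39.8% of the mm9 type, so few of the mouse-named probes were bright enough either. Of the 1836, 401 (21.8%) could be tested, 223 of them human-named, 145 mouse-named and 33 of the mm9 type, and limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05, 20 of them had higher means in IR and 47 lower means, of which 9 and 26 were human-named, 6 and 17 mouse-named and 5 and 4 of the mm9 type. The groups were separated for 20 with higher and 63 with lower IR values, together 20.7%. All tested probes gave 25.8%, and the average over all 10 splits of the arrays is 10%. Differences of at least 2-fold went the other way, with 28 higher and 4 lower, an excess also seen among all tested probes (1208 and 362). With an unadjusted p under 0.05 as well, 6 were higher and 2 lower. Of the 14 tested probes with a RefSeq mRNA accession, 0 were called in either direction by the same limma test, and at an unadjusted p under 0.05 these were Tfrc and Tuba1b with higher means and Gk with a lower mean. The remaining tested probes, 34834 and 291 of the types whose IDs begin with ASMM10P and ASMM10UP, had no gene name in the sources used here.

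Of the probes with separated groups that were well above background on at least 1 array of each group, the 2 with the widest mean difference in each direction were picked after their values were seen. Probe ASMM10P026141 was brighter in IR by a log2 difference of 5.87 in the measured means (limma, Benjamini-Hochberg adjusted p = 0.208), but was well above background on only 2 of the 3 sham arrays, so the size is uncertain. Its IR values were -1.35, 5.29 and 4.49 in replicates 1, 2 and 3, so replicate 1 stayed close to the highest sham value of -1.63. Probe ASMM10P032584 was brighter in IR by a log2 difference of 5.15 in the measured means (limma, Benjamini-Hochberg adjusted p = 0.211), but only 1 sham array measured it above background, so its size is uncertain too. Here too IR replicate 1, at -2.45, lay far below replicates 2 and 3, at 4.28 and 3.35. Probe ASMM10P040651 was 25.5-fold dimmer in IR, a log2 difference of -4.67, and ASMM10P018626 was 11-fold dimmer, with -3.46 (limma, Benjamini-Hochberg adjusted p = 0.202 and 0.205). For both, sham replicate 1 was the lowest of its group, at 1.46 and -0.28. Without sham replicate 1 both dimmer probes were called, with differences of -5.58 and -4.16 (limma, Benjamini-Hochberg adjusted p = 0.0211 and 0.0315), and without IR replicate 1 both brighter probes were called, with 7.95 for ASMM10P026141 and 7.24 for ASMM10P032584 (limma, Benjamini-Hochberg adjusted p = 0.029 and 0.00574). Without IR replicate 2 the differences of the brighter probes fell to 4.63 and 3.87. Normexp background correction gave 4.18, 3.44, -3.80 and -2.28 for ASMM10P026141, ASMM10P032584, ASMM10P040651 and ASMM10P018626. The row as a block, which sets the IR arrays against sham replicate 1 alone, gave 4.45, 5.49, -2.87 and -2.08 in the same order.

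The arrays did not divide cleanly by group. Over the tested probes, sham replicate 1 correlated more closely with IR replicate 1 (r = 0.9905, across probes, which are not independent replicates) than with sham replicates 2 and 3 (r = 0.9783 and 0.9825). Sham replicates 2 and 3 resembled each other (r = 0.9928), and IR replicate 3 was close to both IR replicate 1 (0.989) and IR replicate 2 (0.99), which differed more from each other (0.9772). On the first principal component, which held 52.9% of the variance, sham replicates 2 and 3 lay at 72.9 and 64.0, sham replicate 1 at -2.23, and IR replicates 1, 2 and 3 at -20.8, -65.7 and -48.1.

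**Figure D2:**
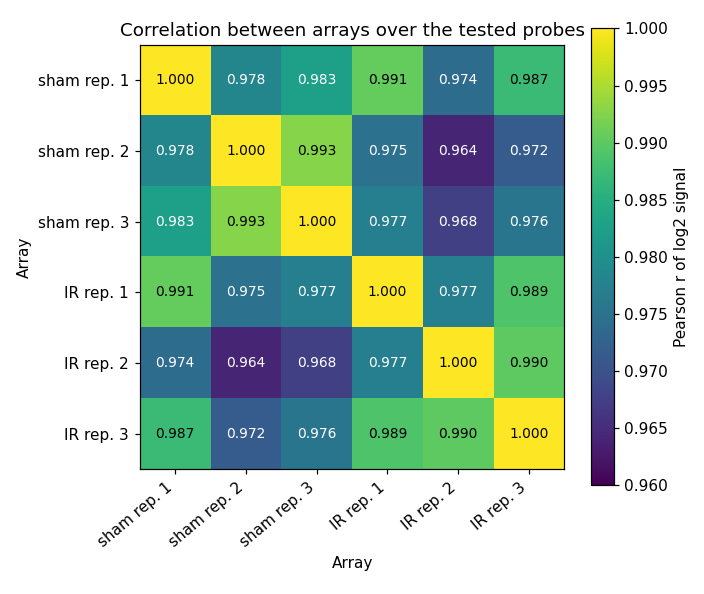
Pearson correlation of normalised log2 signal between each pair of the 6 arrays (both axes) over 35540 tested probes, with the value in each cell and the colour scale starting at 0.96. The cell of sham replicate 1 and IR replicate 1 (0.9905) exceeds those of sham replicate 1 with the other sham arrays (0.9783 and 0.9825).

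Single arrays decided whether probes were called. Without sham replicate 1, 674 probes were called higher and 409 lower in IR. Without IR replicate 1, 550 were called higher and 102 lower. Leaving out any of the other 4 arrays gave 0 calls. The calls made without sham replicate 1 and those without IR replicate 1 had 63 probes in common, all with the same sign, where independent lists of these sizes would share 19.9. Both fits used the other 4 arrays, so part of this overlap comes from shared data. Among the lincRNA-named probes, 13 were called higher and 3 lower without sham replicate 1, and 2 higher and 2 lower without IR replicate 1. No named gene was called in any of these fits.

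**Figure D3:**
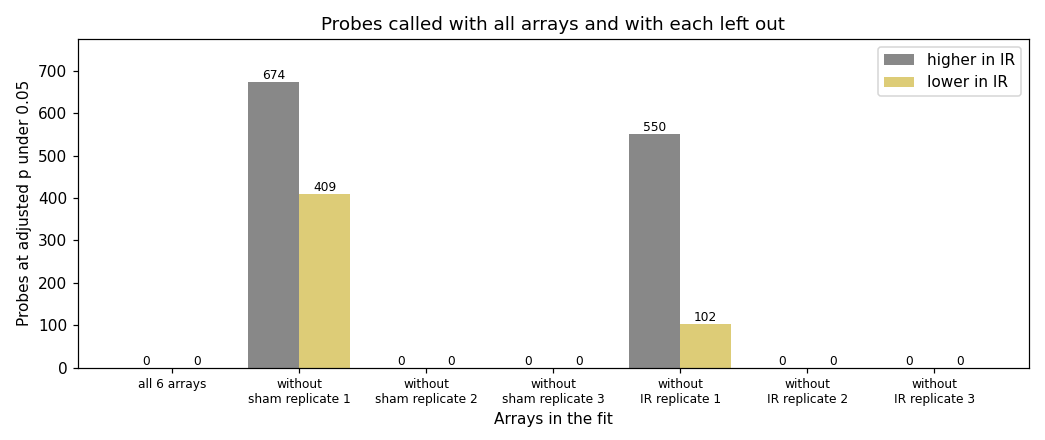
Number of probes with a limma Benjamini-Hochberg adjusted p under 0.05 (vertical axis) in the fit of all 6 arrays and in fits that leave out 1 array each (horizontal axis), with bars for probes higher and lower in IR and the counts above them. Calls appear only without sham replicate 1 (674 higher, 409 lower) or without IR replicate 1 (550 higher, 102 lower).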

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

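Of the spike-in control probes, those whose median signal on every array lay above the negative probes are given. The probe ERCC-00062_278 had a median signal of 144 over the arrays and ERCC-00097_63 one of 27.4, both above 19, the highest 99th percentile of the negative probes on any array. A further control probe, (+)E1A_r60_a107, had a median of 22.3 over the arrays, but its median lay between 11.5 and 36.1 on single arrays and so not above 19 on each. No explanation was tested.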

How the results depend on the processing

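Which alternatives were planned is given with the processing; the row, row 1, split and normexp settings and the gene-by-gene form of array weights were chosen after the data were seen. No probe was called in either direction by limma with quantile normalisation, a median shift, normexp with either normalisation, no filter, a filter on all 6 arrays, trend and robust settings, a 2-fold minimum, a threshold of 0.01, or the block of sham replicate 1, IR replicate 1 and IR replicate 3 against the others. With the authors' values 1 probe was called higher. The row as a block gave 1 higher and 1 lower, and row 1 alone, where the lone sham array is assumed to vary like the IR arrays, 1 lower. Array weights gave 6809 probes higher and 7697 lower, 86 and 96 of the lincRNA-named probes, and 3 and 1 of the RefSeq-named probes (Tfrc, Tuba1b and Hprt higher, Gk lower), but the weight of IR replicate 3 was 8.52 against 0.307 to 1.93 for the others, so that fit rests mostly on 1 array, the one that lay between its group's other arrays. Leaving out 1 array at a time gave 0 to 674 probes higher and 0 to 409 lower, 0 to 13 lincRNA-named probes higher and 0 to 3 lower, with calls only without sham replicate 1 or IR replicate 1. The cause of these changes was not tested. The replicate number as a block gave 0 calls in either direction (smallest adjusted p 0.269). Deviations of same-numbered samples correlated at 0.108, 0.113 and -0.0283, and 2 of the 6 arrays correlated best with their own number, so the numbers were not taken to pair the samples. Tfrc, Tuba1b and Gk kept their direction in every alternative run, of which the filters, the replicate block, the trend and robust settings, the 2-fold minimum and the threshold of 0.01 cannot change it; the others gave 0.31 to 0.55, 0.39 to 0.78 and -1.06 to -0.50, with limma Benjamini-Hochberg adjusted p from 0.00881, 0.0101 and 0.0117 (array weights) to 0.831 (row 1 alone). The sign turned in 1 or more alternatives for B2m, Gapdh, Hsp90ab1, Nono, Ppia and Tbp. The slide as a block was not run, as there was 1 slide, nor were normexp on the mean signal, a column not used here, and the gene list and probe-mean alternatives, which lacked named genes. Signal over background limited the tests to 58.3% of probes.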

Other observations

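The tests on array brightness, exchanged labels and the share of probes outside the other IR arrays in the following paragraphs were written before their results, and those on the row, the control probes, the restricted set of probes and the numbers of all probes called in other splits after the results were seen.

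Single arrays differed from the sham arrays to unequal extents. Against all 3 sham arrays, IR replicate 2 had 1158 probes at least 2-fold above and 755 at least 2-fold below, IR replicate 3 had 522 and 132, and IR replicate 1 had 308 and 63. IR replicates 2 and 3 shared 468 of the probes above sham, and 53 were above in all 3, where the use of the same sham arrays alone gives some overlap. Among sham arrays, replicate 1 had 1078 probes at least 2-fold above the other two and 185 below, numbers of the size seen for IR arrays, although from a comparison with 2 arrays in place of 3. Among the named genes IR replicate 2 lay above IR replicate 1 in 13 of 14, all but Gk, whether the mean was higher in IR, as for Tuba1b, or lower, as for Hsp90ab1, where replicate 1 was the one farthest from the sham mean.

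Sham replicate 1 resembled IR replicate 1 more than its own group. An effect of dim probes alone is argued against, since over the 11847 brightest probes its r with IR replicate 1 still exceeded the higher sham r by 0.00485 (bootstrap standard error 0.00044). An exchange of the labels of these 2 samples would turn the sign of their difference, but across probes the difference of IR replicate 1 minus sham replicate 1 had a slope of 0.128 (standard error 0.005) on the difference of the other arrays. That slope was low, as were those of IR replicates 2 and 3 minus sham replicate 1 (0.223 and 0.321), while pairs with the other sham arrays had slopes from 0.468 to 1.23. The pairs with sham replicate 1 lay within row 1, and all others crossed the rows. Each pair was set against its own remaining arrays, so the slopes do not share a common scale. The standard errors in this paragraph are across probes, which are not independent, and do not measure the spread between kidneys. With 1 pair of samples, an exchange of labels is therefore not excluded. The row of the array stays open, with 3 probes called for it and 5126 at an unadjusted p under 0.05 in limma, since row 2 held only sham arrays and row and animal cannot be told apart there, and a biological difference between this sham kidney and the others, not tested, stays open too.

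IR replicate 3 was the middle array of its group for 61.1% of probes, where chance gives 33.3% and sham replicate 3 reached 47.9% in its own group, and for 11 of 14 named genes; a hypothesis is that its RNA was a mixture of those of IR replicates 1 and 2, a pattern singled out after all sets of 3 arrays had been looked at. On the 215 probes at least 4-fold brighter in IR replicate 2 than in IR replicate 1, IR replicate 3 lay between them on 99.1%. Its median place between them on the linear scale was 0.518 (quartiles 0.479 to 0.556), near the midpoint. A physical mixture acts on every probe, however. On 22.4% of the 255 probes at least 4-fold brighter in IR replicate 1 than in IR replicate 2, IR replicate 3 lay outside the range of these arrays. Its median place on the 255 probes was 0.426 (quartiles 0.102 to 0.527). That direction argues against a mixture as the whole account. Of the 57 probes outside the range, 39 were among those that set sham replicate 1, IR replicate 1 and IR replicate 3 apart. On probes where the sham arrays lay within 2-fold, IR replicate 3 lay outside the other IR arrays on at most 2.52%. This restriction was added after the first result. It removes by construction the probes that speak against a mixture, since sham replicate 1 was at least 4-fold above both other sham arrays on 43 of the 57. On sets of probes picked likewise for IR replicate 2 and a sham array, IR replicate 3 also lay mostly between the 2. It lay outside on at most 2.54%, 4.02% and 2.2% for sham replicates 1, 2 and 3. Its median places there were 0.549 to 0.689. An intermediate response would give the same values, so nothing about a mixture is read from the restricted set. No biological explanation was tested.

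The control probes for Pgk1 with the suffix 5 were brighter in sham replicates 2 and 3 than on the other arrays. The mouse PGK1 suffix 3 minus suffix 5 difference averaged 8.47 on the 4 arrays of row 1 and 7.53 on the 2 of row 2, a gap of 0.94 log2 units (0.939). A general loss of signal far from the 3' end on those 4 arrays would widen the same difference for GAPDH, but the control probes disagreed. That gap was -0.24 for mouse GAPDH and 0.819 for the human-named GAPDH probes, each with no overlap between the rows, and -0.123 for the rat-named ones, so this explanation stays open. The row of the slide and a difference between these animals cannot be told apart, because row 2 held only sham arrays, and no biological explanation was tested.

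With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be had. The real split gave 0 probes higher, 0 lower and 0 lincRNA-named probes in either direction by limma. With counts of 0, all 10 splits must give as many, so these comparisons say nothing about chance; the highest other split gave 126, 1 and 7. At an unadjusted limma p under 0.05 the real split gave 7042 probes and the highest other 4314, so 1 split of the 10, the real one, reached that number. Splits that kept sham replicates 2 and 3, the arrays of row 2, together all gave 1586 probes or more. Those that parted them gave 1532 or fewer. The first place of the real split can therefore not be told apart from an effect of the row. The split with the 126 calls set sham replicate 1, IR replicate 1 and IR replicate 3 against the others. It was singled out as the highest of the other splits. Whether it reflects a structure of the samples apart from group and row was not tested. Those 126 probes were higher in sham replicate 1, IR replicate 1 and IR replicate 3, by a median of 2.51 on the log2 scale. With that split as a block, IR against sham still gave 0 calls by limma, and 6992 probes had an unadjusted p under 0.05.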
